A study of Mus musculus with 12 samples.

How the data were processed

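The series measured RNA in liver of wild-type male C57Bl/6J mice on postoperative day 3 after partial hepatectomy, the surgical removal of part of the liver, with 12 libraries in 4 groups of 3. The groups, taken from the labels, are resection of 70% (PH70), resection of 80% (PH80), the larger resection in an arm named HC (PH80_HC) and the larger resection with G-CSF and HNF4a (PH80_G+H). The meaning of HC, and the dose, route and timing of G-CSF and HNF4a, are not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit from Qiagen and libraries were made from 100 ng of total RNA with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

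Per the submitters' processing notes, the genome build was GRCm38 (mm10) and DESeq2 was used. The aligner, the counting tool and the gene annotation are not given in the sources used here. The deposited table holds 1 value per gene and library, a normalised signal that corresponds to read counts divided by 1 size factor per library. This unit was read from the values: in each library 100% of the values came out as whole multiples of 1 read within 0.01 (largest distance 0.000939). The implied size factors equalled those recomputed with the DESeq2 method from the recovered reads. Recovered reads ranged from 9.72 M (PH70 replicate 3) to 44.5 M (PH80_G+H replicate 2) per library, and library depth sets the precision of genes with few reads. The table lists 13554 genes by symbol, the lowest mean value over the libraries is 1.01, and it holds 0 mitochondrially encoded genes. Genes below that level, and Csf3, the gene of G-CSF, are therefore not analysed here.

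Values were analysed as log2(value + 1) in genes with a value of at least 10 in at least 3 libraries, which left 12570 genes. A fold change is on this scale and understates the change of genes with low values. Limma (version 3.58.1 in R 4.3.3) was fitted to all 12 libraries with group as the single factor, so that the 4 groups share 1 estimate of the spread, with an intensity trend in the empirical Bayes step. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested in a comparison and a threshold of 0.05. The 6 comparisons between groups and 1 moderated F test over the 4 groups were made this way. Because the deposited values are not whole counts, the count models edgeR (4.0.16, quasi-likelihood test) and DESeq2 (1.42.0, Wald test) were run as alternatives on the recovered reads. Samples, comparisons, tests, filters, gene lists, the naming rule and the first set of alternatives below were fixed before the data were examined.

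Gene lists covered 36 themes with 659 entries, of which 617 are in the table and 604 were tested. They are S phase and DNA replication, mitosis, p53 targets, secreted hepatocyte proteins and coagulation factors, hepatocyte transcription factors, drug metabolism, bile acid synthesis and transport, urea cycle and amino acid catabolism, gluconeogenesis and glycogen, fatty acid oxidation and ketogenesis, lipogenesis, cholesterol synthesis, hypoxia response, angiogenic signalling, acute phase response, the unfolded protein and integrated stress response, oxidative stress response, interferon response, growth hormone and male-biased genes, circadian clock, immediate early genes, and apoptosis and necroptosis. Marker lists covered pan-endothelial, sinusoidal endothelial, stellate (with matrix), cholangiocyte and progenitor, fetal liver, macrophage, neutrophil, lymphocyte, erythroid, pericentral hepatocyte and periportal hepatocyte genes, and pancreas, muscle, and fat with mesothelium as other tissues. Each list was tested with camera at a preset correlation between genes of 0.01, with camera at a correlation estimated from the data, and with fry, with Benjamini-Hochberg adjustment over the 36 lists of a comparison. Camera compares a list with all other genes. Fry tests whether the members move, on balance, in 1 direction, and does not compare them with other genes.

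Genes are named by a rule. For PH80 against PH70 and for each treated arm against PH80, the text names up to 8 genes per direction with the largest change among genes past the threshold, with a mean value of at least 50, no overlap between the libraries of the compared groups, and a symbol that is not of a predicted gene. It also names up to 4 members with the smallest adjusted p of each list with a called member or a list call, some of which are left out for length. In every case it names Hnf4a, Csf3, Csf3r, Mki67, Vegfa, Alb, Cyp7a1, Stab2 and Pecam1. The other comparisons name up to 4 genes per direction. Genes named outside this rule are marked as chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38, in which 12538 of the tested symbols match 1 gene. Genes of the Mup, Cyp2c and Cyp2d families have near-identical copies between which reads can be shared, so their values are uncertain, as are those of overlapping antisense genes, since the strand setting of the counting is not given in the sources used here.

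Alternatives fixed in that way were pseudocounts of 0.5 and 8, no filter and a mean value of at least 50 as a filter, scaling of every library to the same total with and without the 50 most abundant genes, quantile normalization, the empirical Bayes step without a trend or in robust form, the replicate number as a block, fits to the compared groups alone, the count models, a fold change minimum, and leaving out each library in turn. Added after seeing the data were removal of each library's trend with transcript length and GC share (natural splines with 4 degrees of freedom for each, 12557 genes with a length) and a fit without the library with the steepest length trend of each group. The relation of the first principal component with transcript length, over all libraries and within groups, the simulated counts of opposite signs and shared genes, and the split of the PH80 libraries between comparisons were chosen after seeing the data too. Each library was also compared with the others of its group. Spearman correlations were between 0.964 and 0.991, and the lowest chi-square per degree of freedom between libraries of a group was 29.3, so no library duplicates another within sampling noise. Drawings were made with Python 3.11.15 and matplotlib 3.10.9.

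The fit was tested on simulated counts drawn from the real means, dispersions and library sizes, with 12570 genes of which 200 with a mean value of at least 50 were changed. For PH80 against PH70 it recovered 34.3% of genes changed 2-fold, 95.5% changed 4-fold and 100% changed 8-fold, with 5.56% false calls. For PH80_HC against PH80 these were 52.2%, 89.6% and 98.5%, with 5.33% false calls, and for PH80_G+H against PH80 they were 40.3%, 97.0% and 100%, with 3.07% false calls. In simulated data the list test found the shifted list in each of these comparisons, with a preset and with an estimated correlation, and called none of the other lists at the preset one. Real libraries of a group differ along shared axes that the simulation lacks, so these shares hold for independent genes alone.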

Results

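Liver RNA was sequenced on postoperative day 3 from mice that had lost 70% (PH70) or 80% (PH80) of the liver, and from mice with the larger resection in an arm named HC (PH80_HC) or with G-CSF, the growth factor of granulocytes, and HNF4a, a hepatocyte transcription factor (PH80_G+H). Each group had 3 libraries. The depth in recovered reads was 38.5, 13.4 and 9.72 M for PH70 replicates 1 to 3, 15.0, 28.6 and 20.5 M for PH80, 36.0, 40.7 and 23.5 M for PH80_HC, and 13.1, 44.5 and 32.6 M for PH80_G+H. Values are normalised reads, errors are SD over 3 libraries unless named as SE, and adjusted p-values are from limma with Benjamini-Hochberg adjustment. Albumin transcripts took between 6.74% and 11.7% of the values of a library, and the 50 most abundant genes took between 33.8% and 42.7%. Of 12570 genes tested, 232 differed among the 4 groups by the moderated F test (2398 at an unadjusted p under 0.05, 215 by edgeR and 1226 by DESeq2).

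Libraries also differed within groups, along an axis tied to transcript length. The first principal component held 29.9% of the variance, and its scores were correlated with each library's slope of expression on transcript length (Pearson r = -0.895, permutation p = 6e-05, Spearman rho = -0.748, permutation p = 0.00734, over 12 libraries). Without the 2 libraries farthest on that component r was -0.796. For deviations from the group means r was -0.844 (exact permutation p = 0.00926 over 1296 permutations within groups), rho was -0.825 (exact permutation p = 0.0123), and r was -0.759 without the 2 libraries farthest in that measure. The component is also tied to the first comparison, as each PH80 library scored above each PH70 library (lowest -7.28 in PH80, highest -12.2 in PH70). Longer transcripts were relatively higher in PH80_G+H replicate 2 (slope 0.185 on the log2 scale per doubling of length) and PH70 replicate 3 (0.172), while they were lower in PH80_HC replicate 3 (-0.191) and PH80 replicate 1 (-0.129). The 79 ribosomal protein genes, which have short transcripts, lay at -1.12 in PH70 replicate 3, -0.882 in PH80_G+H replicate 2, 0.515 in PH80 replicate 1 and 1.16 in PH80_HC replicate 3, as mean log2 deviation from the mean of all libraries. They also lay at -0.625 in PH70 replicate 2 and 0.43 in PH80 replicate 2, where the slopes on length were smaller (0.0605 and 0.00451). The 137 genes called higher in PH80 than in PH70 had a median transcript length of 1583.5 bases and the 343 called lower one of 2657.5, against 2166 for all tested genes.

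**Figure D1:**
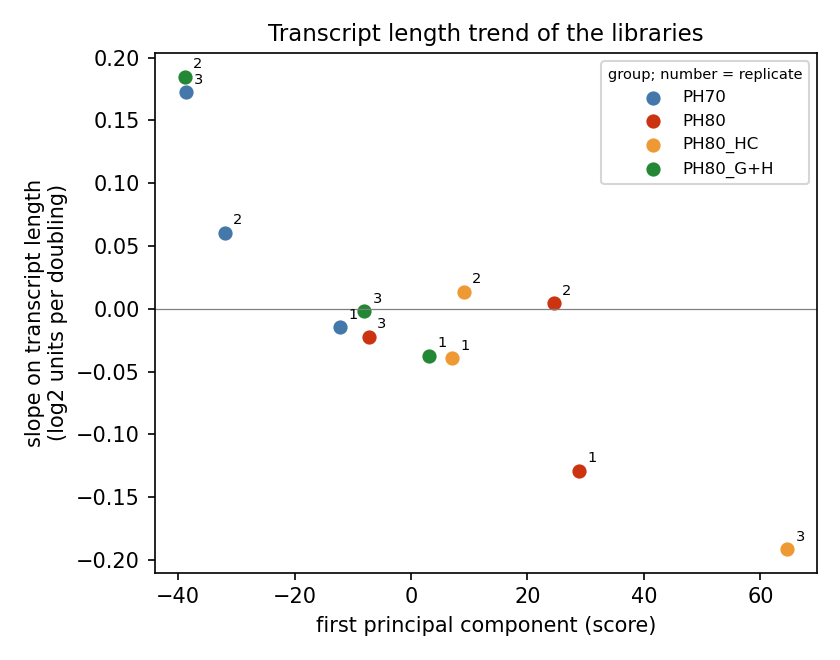
Each point is 1 of the 12 libraries, coloured by group and numbered by replicate, with its score on the first principal component on the x axis and its slope of expression on transcript length (log2 units per doubling) on the y axis. PH80_HC replicate 3 (-0.191) and PH80_G+H replicate 2 (0.185) lie at the ends of the slopes. Libraries of 1 group are spread along the axis, and each PH80 library lies above each PH70 library on the component.

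The first comparison asks what the larger resection did to the remnant liver, set against the smaller one. In PH80, 343 genes fell and 137 rose relative to PH70 (2693 of 12570 genes had an unadjusted p under 0.05), and 224 and 114 of these changed at least 2-fold. Rgs16, a regulator of G protein signalling (chromosome 1, 153740349 to 153745468), was 57.4-fold lower, at 7.13 ± 4.21 in PH80 against 433 ± 78.1 in PH70 (log2 change -5.84, SE 0.80, adjusted p = 0.00352, n = 3 per group). Cyp8b1, the enzyme needed for cholic acid (chromosome 9, 121914356 to 121916305), was 20.7-fold lower, at 391 ± 338 against 4759 ± 1082 (adjusted p = 0.0159). Dbp, a clock-driven transcription factor (chromosome 7, 45705088 to 45710203), was 14.3-fold lower, at 92.1 ± 39.8 against 1375 ± 721 (SE 0.40 on the log2 scale, adjusted p = 0.000695). Among the highest increases were Sult1e1, the estrogen sulfotransferase (27.7-fold, 428 ± 504 against 9.8 ± 7.13, adjusted p = 0.0264), and Prom1, a surface marker of progenitor and bile duct cells (chromosome 5, 43993620 to 44102032, 15.9-fold, 326 ± 105 against 21 ± 13, adjusted p = 0.00716).

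Other genes with large increases in PH80 were Ly6d (14.9-fold, 5970 ± 2946 against 463 ± 397, chromosome 15, 74762056 to 74763620), Wfdc3 (14.3-fold), the aldo-keto reductase Akr1b7 (13.8-fold) and Gldn (10.1-fold). The transcription factor Mybl1 (6.28-fold, 710.4 ± 84.6 against 118 ± 50.4, adjusted p = 0.000929, chromosome 1, 9667415 to 9700209) rose, as did Slc51b, a subunit of the basolateral bile acid exporter (5.98-fold, 738 ± 395 against 113 ± 14.4). Further decreases were seen in the sulfotransferase Sult2a8 (13.9-fold, adjusted p = 0.0497, lost in 15 of 27 alternatives), the uridine phosphorylase Upp2 (11.8-fold, 354 ± 133 against 4398 ± 2044, chromosome 2, 58567298 to 58792971) and Clec2h (10.2-fold). Nr1d1, the clock repressor REV-ERB alpha (9.32-fold, 411 ± 262 against 3335 ± 600.3, chromosome 11, 98767932 to 98775333), and the interferon-inducible Gbp10 (7.52-fold) fell too. The 480 calls became 61, 172 and 274 without PH70 replicate 2, 1 or 3, 125 and 157 without PH80 replicate 1 or 2, 306 without PH80_G+H replicate 3 and 727 without PH80_HC replicate 3. They became 237 with every library at the same total (127 up and 110 down), 302 without the library with the steepest length trend of each group and 952 with DESeq2.

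Hepatocyte function genes were lower in PH80 as groups. Of 23 drug metabolism genes 8 fell, or 12 adjusted over the list alone, led by Cyp2e1, the ethanol-inducible cytochrome P450 (4.14-fold, 14958 ± 7763 against 58813 ± 17132, adjusted p = 0.00761, chromosome 7, 140763739 to 140774987), Cyp2a5 and Cyp2f2 (log2 changes -1.32 and -1.49). The list was past the threshold with camera at the preset correlation (adjusted p = 1.72e-06), and had an adjusted p = 0.284 with an estimated correlation. Among 18 genes of bile acid synthesis and transport 5 fell and 1, Slc51b, rose (10 and 1 adjusted over the list alone), with Slc10a1, the bile acid uptake carrier, 2.78-fold lower. That list had an adjusted p = 7.08e-05, and an adjusted p = 0.284 with an estimated correlation. Of 14 genes of gluconeogenesis and glycogen 3 fell, or 6 adjusted over the list alone, among them G6pc, which releases glucose (3.63-fold, 1898 ± 512 against 6836 ± 1567), and Gys2, the liver glycogen synthase (955 ± 230.5 against 2410 ± 372). That list had an adjusted p = 2.81e-06, and an adjusted p = 0.175 with an estimated correlation. Of 20 genes of fatty acid oxidation and ketogenesis 3 fell (3 adjusted over the list alone), among them Cpt1a with a log2 change of -1.18. The list had an adjusted p = 0.000255, and an adjusted p = 0.538 with an estimated correlation. Tdo2 and Sardh (the latter lost in 16 of 27 alternatives) were the 2 of 25 urea cycle and amino acid catabolism genes that fell (7 adjusted over the list alone). Here the list had an adjusted p = 0.00699, and an adjusted p = 0.599 with an estimated correlation.

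Hepatocyte transcription factors and pericentral markers were lower too, at the preset correlation. Of 15 hepatocyte transcription factors, Cebpa (2748 ± 922 against 6733 ± 91.5, 2.56-fold lower, adjusted p = 0.00814) and Ppara (3.17-fold lower, adjusted p = 0.0142) fell, or 3 adjusted over the list alone. At the preset correlation the list adjusted p was 0.0163, and the list had an adjusted p = 0.284 with an estimated correlation. Hnf4a itself was at 10142 ± 2614 in PH80 and 13331 ± 1938 in PH70 (log2 difference -0.42, SE 0.23, adjusted p = 0.316). Of 16 pericentral hepatocyte markers 5 fell, or 8 adjusted over the list alone, including Glul, the glutamine synthetase of cells at the central vein (2.32-fold, 6509 ± 2418 against 14667 ± 3135), and the glutamate transporter Slc1a2 (log2 change -1.36). For the list, camera gave an adjusted p = 1.3e-05, and an adjusted p = 0.284 with an estimated correlation. Among 19 growth hormone and male-biased genes 4 fell, or 9 adjusted over the list alone, including C8b and the receptor Ghr (log2 changes -1.35 and -1.30). The list had an adjusted p = 1.72e-06, and an adjusted p = 0.284 with an estimated correlation. The 24 secreted hepatocyte proteins and coagulation factors had a median log2 difference of -0.33 with list adjusted p = 0.000141, and adjusted p = 0.538 with an estimated correlation. None of the 24 passed alone in limma, with 8 at an unadjusted p under 0.05, 0 by edgeR and 5 by DESeq2, and 0 passed adjusted over the list alone. In limma without the intensity trend Apoh had an adjusted p = 0.0385, and Proc, F5 and F2 had 0.0827, 0.136 and 0.0781. Alb itself had a log2 difference of -0.61, with each PH80 value below each PH70 value. With the intensity trend its SE was 0.79 (adjusted p = 0.688), without the trend the SE was 0.203 (adjusted p = 0.13), and the adjusted p was 0.336 by edgeR and 0.0481 by DESeq2. For Cyp7a1, the rate-limiting enzyme of bile acid synthesis, the log2 difference was -1.98 (SE 0.89, adjusted p = 0.217).

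Clock genes changed in both directions in PH80. Of 15 genes 6 fell and 2 rose (7 and 2 adjusted over the list alone). At the preset correlation the list adjusted p was 0.00271, and the list had an adjusted p = 0.379 with an estimated correlation. Besides Dbp and Nr1d1, Bhlhe41 fell 15.9-fold (3.88 ± 2.85 against 72.5 ± 28.7) and Tef 3.51-fold (506 ± 72.5 against 1844 ± 630.3, adjusted p = 0.00656). The members that rose, named here after their values were seen, were Npas2 (164 ± 21.5 against 45.3 ± 26.8, log2 change 1.97, SE 0.35, adjusted p = 0.0109) and Cry1 (186 ± 42.7 against 70.4 ± 14.2, log2 change 1.38, adjusted p = 0.00909), which peak at another time of day than Dbp and Nr1d1. The time of day of sampling is not given in the sources used here. Of 13 immediate early genes 3 fell, including Dusp1 (log2 change -2.02, SE 0.29, adjusted p = 0.00446), and the list had an adjusted p = 0.0592.

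**Figure D2:**
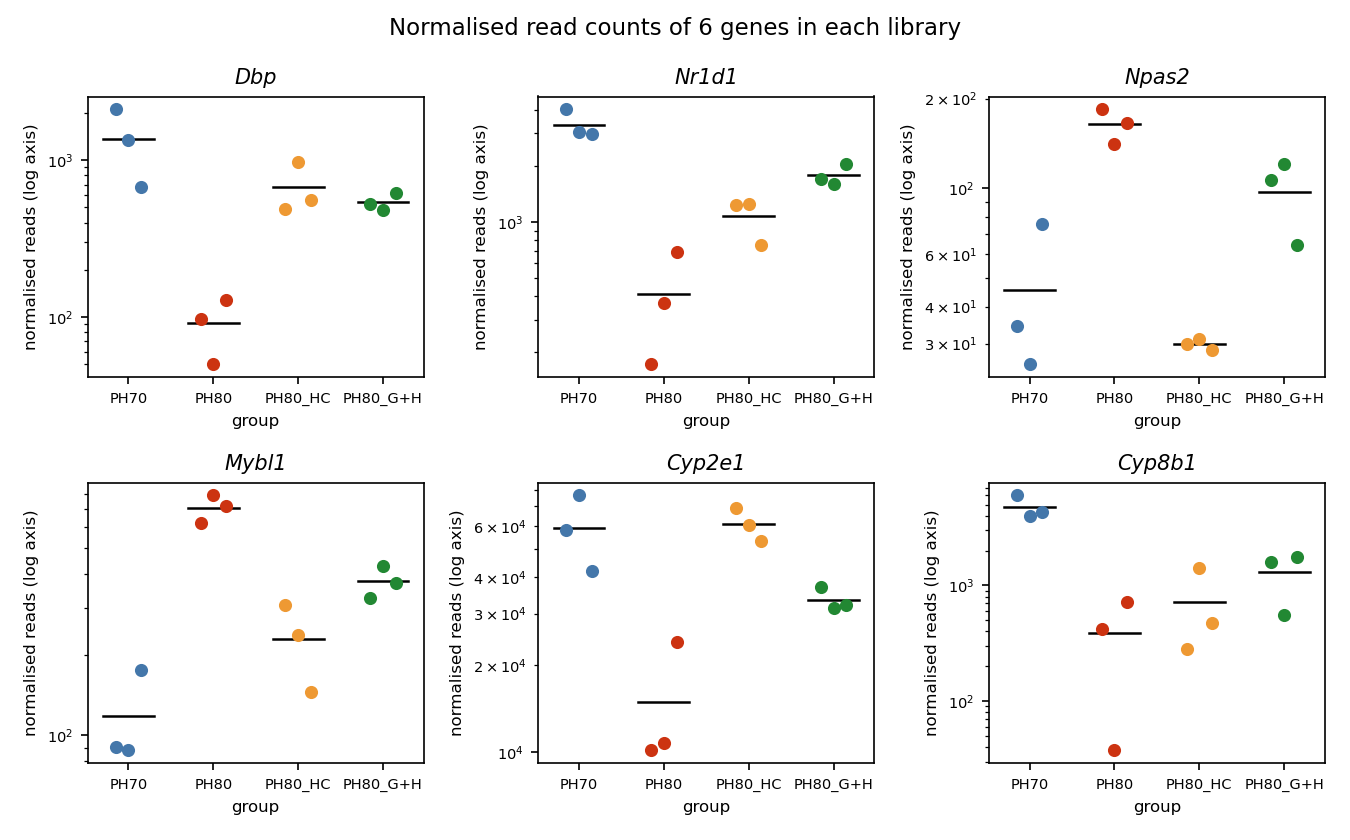
Points are normalised reads of 6 genes in each library on a log axis, by group, with a line at the group mean. Dbp, Nr1d1, Cyp2e1 and Cyp8b1 were lower in PH80 than in PH70 (92.1 against 1375, 411 against 3335, 14958 against 58813 and 391 against 4759 on average), and Npas2 and Mybl1 were higher (164 against 45.3 and 710.4 against 118).

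Mitosis genes were higher in PH80 as a group, at the preset correlation. All 29 had a higher mean in PH80 (median log2 difference 0.64, list adjusted p = 3.71e-07, and adjusted p = 0.599 with an estimated correlation). Of these Cdk1, the kinase that starts mitosis, passed alone (2.28-fold, 2486 ± 699 against 1068 ± 92.7, adjusted p = 0.0305), and 7 passed adjusted over the list alone. The mean of the list above PH70 was 1.38 in PH80 replicate 2, 0.54 in replicate 3 and 0.32 in replicate 1 on the log2 scale. Among 30 genes of S phase and DNA replication Ccne1, the cyclin of S phase entry, rose 2.65-fold (309.8 ± 75.9 against 114 ± 6.06, adjusted p = 0.00761) and Mcm10, which helps load replication factors, fell (log2 change -1.76, adjusted p = 0.0138), with list adjusted p = 0.079. Mki67, a marker of cycling cells, was at 1948 ± 1016 in PH80 and 1211 ± 47.2 in PH70 (log2 difference 0.57, SE 0.33, adjusted p = 0.329). Afp, the fetal albumin-like protein (4.03-fold, 449.9 ± 14.4 against 111 ± 9.4), and Scd2 (lost in 18 of 27 alternatives) rose among 7 fetal liver markers, or 3 adjusted over the list alone. For the list, camera gave an adjusted p = 0.0191, and an adjusted p = 0.284 with an estimated correlation. Of 16 p53 targets Gdf15, a stress cytokine, fell (3.56-fold, 512 ± 118 against 1829 ± 425, adjusted p = 0.00317), with list adjusted p = 0.639.

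Endothelial and angiogenic genes, which bear on vascular damage, showed few single calls. In angiogenic signalling Id1 rose (2.72-fold, 1359 ± 434 against 479.8 ± 11.2, adjusted p = 0.0257) and the coreceptors Nrp1 and Nrp2 fell (log2 changes -0.78 and -1.09) among 22 genes, with list adjusted p = 0.496. The calls of Id1, Nrp1 and Nrp2 were lost in 8, 6 and 13 of 27 alternatives. Those of Id1 and Nrp2 were lost once the trend with transcript length and GC was removed. Each of these calls was lost without the library with the steepest length trend of each group. The 20 sinusoidal endothelial markers had a median log2 difference of -0.26 (list adjusted p = 0.0485, 0.178 once the trend with transcript length and GC was removed, and adjusted p = 0.782 with an estimated correlation), and the 18 pan-endothelial markers one of -0.16 (list adjusted p = 0.257). No member of these 2 lists passed alone in limma (7 and 2 had an unadjusted p under 0.05, 0 and 0 passed by edgeR, 1 and 0 by DESeq2). Values for Vegfa, Stab2 and Pecam1 were -0.05, -0.30 and -0.15 as log2 differences, with adjusted p = 0.945, 0.454 and 0.723.

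Neutrophil and macrophage markers were higher in PH80 as groups, at the preset correlation. Between libraries, the mean of each list differed by 1.22 (SE 0.836) and 0.421 (SE 0.367) on the log2 scale, both within 2 SE of 0. All 15 neutrophil markers had a higher mean (median log2 difference 0.90, list adjusted p = 0.00412, and adjusted p = 0.682 with an estimated correlation), with 1 past adjusted over the list alone, and their mean above PH70 was 3.09 in PH80 replicate 2 but 0.66 in replicate 1 and -0.08 in replicate 3. The 19 macrophage markers had a median of 0.39 (list adjusted p = 0.0397, 0.0646 once the trend with transcript length and GC was removed, and adjusted p = 0.756 with an estimated correlation). Csf3r, the G-CSF receptor, had a log2 difference of 0.40 (adjusted p = 0.723), and Csf3 is not in the table. The remaining lists did not pass. Their list adjusted p-values were 0.0936 for periportal markers, 0.179 for the acute phase response, 0.224 for oxidative stress, 0.257 for interferon response, 0.355 for hypoxia response and 0.36 for cholesterol synthesis. They were 0.559 for stellate cell and matrix, 0.68 for lymphocyte, 0.683 for cholangiocyte and progenitor, 0.722 for the unfolded protein and integrated stress response, 0.922 for apoptosis and necroptosis and 0.977 for lipogenesis. For erythroid markers it was 0.907, with the test and mean (-0.03) below 0 and the median (0.41) above. For pancreas it was 0.079 (1 gene), for muscle 0.907, and for fat and mesothelium 0.898, with the test above 0 and the mean (-0.04) and median (-0.17) below. Lipogenesis held the lipid droplet gene Pnpla3, which rose (5.9-fold, adjusted p = 0.0138), and Dgat2, which fell (log2 change -0.92), and the stress list held Trib3, which fell (log2 change -1.91). Pdk1 of hypoxia response, Gclc of oxidative stress and Bmf of apoptosis and necroptosis fell too (lost in 9, 14 and 7 of 27 alternatives). So did Cela2a of pancreas (lost in 11 of 26). In the 13 lists without a call, 42 of 207 genes had an unadjusted p under 0.05, with 0 calls by edgeR and 16 by DESeq2.

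**Figure D3:**
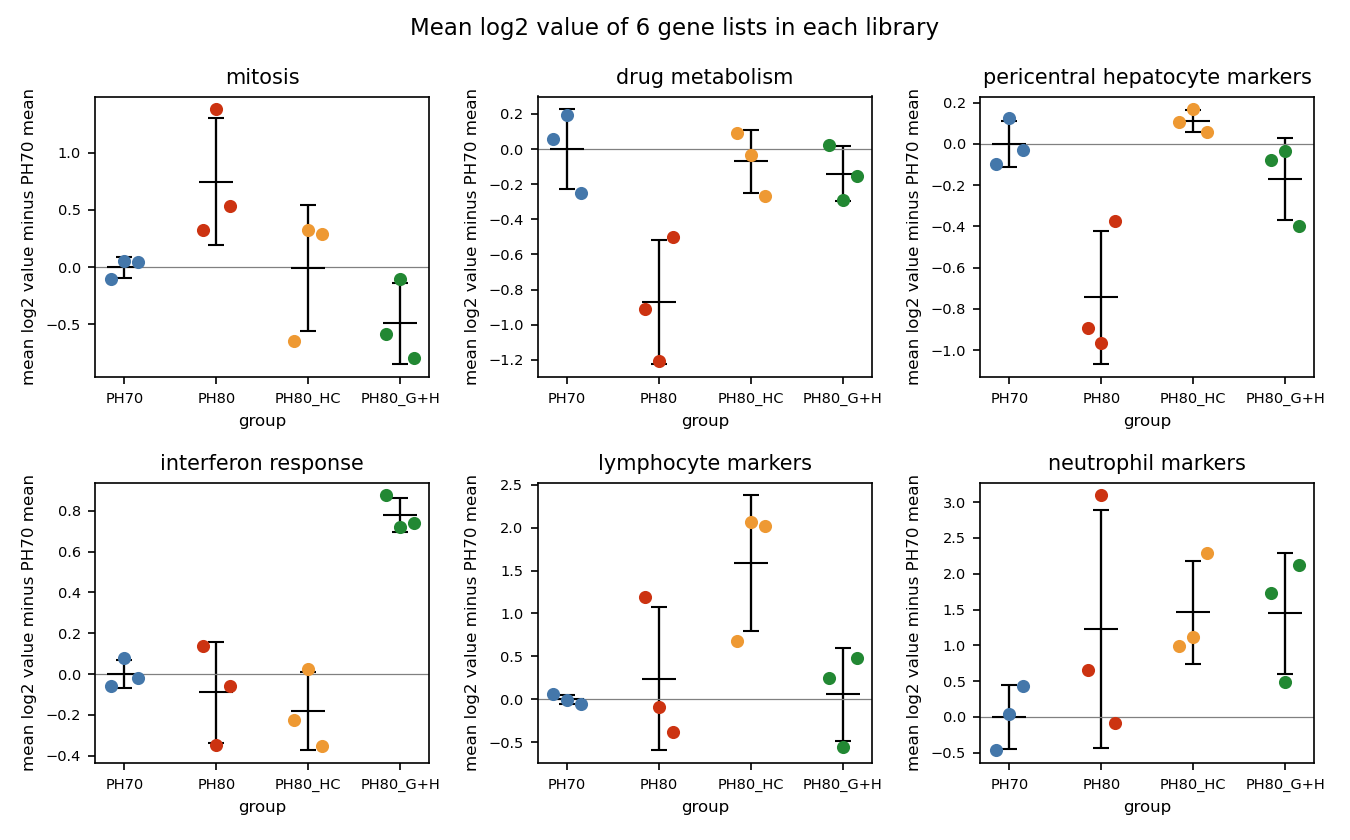
Points are the mean log2 value of 6 gene lists in each library minus the PH70 group mean, by group, with the group mean and SD (n = 3) in black. Mitosis genes were highest in PH80 replicate 2 (1.38), interferon response genes lay between 0.72 and 0.88 in PH80_G+H, and drug metabolism genes lay between -1.20 and -0.50 in PH80.

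The arm named HC was compared with PH80 to ask how it altered the remnant after the larger resection. In PH80_HC, 82 genes rose and 30 fell relative to PH80 (1792 at an unadjusted p under 0.05). The highest rise among the genes that met the naming rule was that of Tgtp1, an interferon-induced GTPase (chromosome 11, 48985327 to 48994172), at 164 ± 122 against 16.7 ± 4.7 (7.72-fold, SE 0.48 on the log2 scale, adjusted p = 0.0157). Dbp (676 ± 264 against 92.1 ± 39.8, 7.45-fold, adjusted p = 0.0118), Upp2 (2327 ± 1215, 6.34-fold) and Cyp2e1 (60912 ± 8186 against 14958 ± 7763, 4.39-fold, adjusted p = 0.0155) also rose. The largest decreases by that rule were in Inava (53.4 ± 13.1 against 421 ± 30.4, 7.91-fold, adjusted p = 0.00917, chromosome 1, 136213531 to 136234264) and the clock activator Npas2 (29.9 ± 1.26 against 164 ± 21.5, 5.31-fold, adjusted p = 0.0142, chromosome 1, 39193731 to 39363236).

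Immune genes among the calls were Cd74, the invariant chain of class II antigen presentation (3861 ± 2253 against 672 ± 426, 5.78-fold, adjusted p = 0.0344, chromosome 18, 60803848 to 60812652), and Jchain, the joining chain of antibodies (192 ± 47.6 against 36.0 ± 23.1, 5.9-fold). Socs2, a target of growth hormone signalling, rose 4.57-fold (741 ± 406 against 149.6 ± 51.3), and the cytochrome P450 genes Cyp2c37 and Cyp2c54, which have near-identical copies, had log2 changes of 2.77 and 2.75. Mup1 and Mup7, urinary protein genes with near-identical copies (log2 changes -2.05 and -2.02), Amn, Icosl, Nat8f5 and Atp4a (-2.05, -1.87, -1.79 and -1.74) were lower. The 112 calls became 28 and 69 without PH80 replicate 1 or 3, 39, 68 and 71 without PH80_HC replicate 1, 2 or 3, 51 without PH70 replicate 2 and 44 without PH80_G+H replicate 3. They became 72 with every library at the same total (17 up and 55 down), 55 when that total left out the 50 most abundant genes (22 up and 33 down), 219 with the length and GC trend removed, 61 without the library with the steepest length trend of each group, 2 with the compared groups alone and 508 with DESeq2.

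Hepatocyte function lists were higher in PH80_HC than in PH80, each past the threshold at the preset correlation and with an adjusted p of at least 0.229 with an estimated correlation. Of 16 pericentral markers 3 rose, or 11 adjusted over the list alone, among them Glul (16370 ± 2417 against 6509 ± 2418, 2.62-fold, adjusted p = 0.0377, lost in 16 of 27 alternatives) and Slc1a2 (log2 change 1.49). The list had an adjusted p = 1.39e-08, and an adjusted p = 0.229 with an estimated correlation. Drug metabolism had 3 of 23 genes that rose (8 adjusted over the list alone). At the preset correlation the list adjusted p was 5.9e-07, and the list had an adjusted p = 0.272 with an estimated correlation. Bile acid synthesis and transport had 2 of 18, Cyp27a1 and Slc27a5 (log2 changes 1.26 and 1.14, and 7 adjusted over the list alone). For the list, camera gave an adjusted p = 1.43e-05, and an adjusted p = 0.229 with an estimated correlation. Fatty acid oxidation had Cyp4a14 (log2 change 2.08, lost in 13 of 27 alternatives). The list had an adjusted p = 0.000265, and an adjusted p = 0.378 with an estimated correlation. Secreted hepatocyte proteins (median 0.60, 4 of 24 adjusted over the list alone) had list adjusted p = 1.07e-09, and adjusted p = 0.272 with an estimated correlation. The urea cycle and amino acid list (5 of 25 adjusted over the list alone), gluconeogenesis and glycogen (4 of 14) and hepatocyte transcription factors had list adjusted p = 0.000433, 0.000899 and 0.011, and adjusted p = 0.341, 0.229 and 0.229 with an estimated correlation. Growth hormone and male-biased genes, with 1 member that rose, Socs2, had list adjusted p = 0.031, and adjusted p = 0.522 with an estimated correlation. DESeq2 called 3 members of that list higher and 1 lower. The list pools targets of growth hormone with male-biased genes, which were not tested apart. Mup1 and Mup7, which are not in the list, fell. In the clock list Dbp and Tef (log2 change 1.70) rose and Npas2 fell (8 and 2 adjusted over the list alone). At the preset correlation the list adjusted p was 0.00702, and the list had an adjusted p = 0.341 with an estimated correlation. Hnf4a was at 14092 ± 1691 (log2 difference 0.50, SE 0.23, adjusted p = 0.352).

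Mitosis genes were lower in PH80_HC, with all 29 below PH80 on average (median log2 difference -0.75, list adjusted p = 2.25e-10, and adjusted p = 0.341 with an estimated correlation). Of these, 0 passed alone in limma, 17 had an unadjusted p under 0.05, 0 passed by edgeR and 3 by DESeq2, and 8 passed adjusted over the list alone. The mean of the list above PH70 was -0.64, 0.32 and 0.29 in PH80_HC replicates 1 to 3, against 0.32, 1.38 and 0.54 in PH80, so that 2 PH80_HC libraries were level with PH80 replicate 1. Cdk1 and Mki67 had log2 differences of -0.86 and -0.36 (adjusted p = 0.159 and 0.679). Lymphocyte markers were higher, 16 of 17 with a positive difference (median 1.49, list adjusted p = 5.9e-07, and adjusted p = 0.341 with an estimated correlation), and 9 passed adjusted over the list alone. Their mean above PH70 was 0.68, 2.07 and 2.01 in PH80_HC replicates 1 to 3, and 1.19, -0.09 and -0.38 in PH80. Erythroid markers (4 up and 1 down of 5 adjusted over the list alone) were higher with list adjusted p = 0.00457, and adjusted p = 0.29 with an estimated correlation, but turned to lower with the stricter filter (adjusted p = 0.901). Macrophage markers (median 0.37) had list adjusted p = 0.026, and adjusted p = 0.522 with an estimated correlation.

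Stellate cell and matrix genes were lower (median -0.76, 4 of 22 adjusted over the list alone, list adjusted p = 1.45e-06, and adjusted p = 0.341 with an estimated correlation), with Acta2, the actin of activated stellate cells and smooth muscle, at a log2 difference of -2.28 (SE 0.61, adjusted p = 0.101). Cholesterol synthesis, in which all 20 genes lay below PH80 (median -0.60), had list adjusted p = 6.86e-05, and adjusted p = 0.414 with an estimated correlation. Angiogenic signalling (median -0.18) had list adjusted p = 0.0226, and adjusted p = 0.425 with an estimated correlation. The acute phase list, with Crp up (log2 change 1.09, lost in 17 of 27 alternatives), had list adjusted p = 0.00268, and adjusted p = 0.522 with an estimated correlation. The 1 pancreas gene had list adjusted p = 0.0441, 0.0707 once the length and GC trend was removed, and adjusted p = 0.272 with an estimated correlation. The other 17 lists had adjusted p-values from 0.0578 to 0.776, including 0.776 for sinusoidal endothelial, 0.514 for pan-endothelial, 0.426 for neutrophil and 0.569 for interferon response genes, of which Gbp2 rose and Oasl1 fell (log2 changes 1.21 and -1.51). Hypoxia response (list adjusted p = 0.286) held Angptl4, a lipase inhibitor, which rose (log2 change 1.87, lost in 16 of 27 alternatives). Log2 differences of Vegfa, Stab2, Pecam1, Csf3r, Alb and Cyp7a1 were -0.24, 0.26, -0.22, 0.03, 0.57 and -0.26, none past the threshold in limma. In the 27 lists without a call, 118 of 431 genes had an unadjusted p under 0.05, with 1 call by edgeR and 42 by DESeq2.

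PH80_G+H was compared with PH80 to ask what G-CSF with HNF4a did after the larger resection. Relative to PH80, 14 genes rose and 1 fell (1316 at an unadjusted p under 0.05). Cyp26b1, which degrades retinoic acid (chromosome 6, 84571414 to 84593908), rose 7.81-fold, to 267 ± 126 against 32.0 ± 14.5 (SE 0.44 on the log2 scale, adjusted p = 0.0243). Upp2 (2412 ± 959.7, 6.67-fold), Dbp (541 ± 68.4, 6.22-fold, adjusted p = 0.0243) and Nr1d1 (1782 ± 243 against 411 ± 262, 5-fold) rose. Ifit1, an interferon-induced antiviral gene (408 ± 62.5 against 132 ± 47.2, 3.21-fold, adjusted p = 0.0243, chromosome 19, 34640871 to 34650009), and Lpin1, a phosphatidate phosphatase (1119 ± 356 against 260.2 ± 12.4, 4.13-fold, chromosome 12, 16535669 to 16610966), rose as well.

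Further increases were in Gbp6 (171 ± 18.5 against 41.7 ± 14.6, 4.17-fold), the fructose transporter Slc2a5 (3.7-fold) and the kinase Pim3 (1489 ± 442 against 399 ± 76.7, 3.67-fold). Dhx58 and B3galt1, chosen after their values were seen, had log2 changes of 1.32 and 1.27. The gene that fell was Gpx7, a peroxidase of the endoplasmic reticulum (391 ± 42.2 against 921 ± 152, 2.34-fold lower, adjusted p = 0.0342, chromosome 4, 108400390 to 108406961). No call was left without PH70 replicate 2, PH80 replicate 1, PH80 replicate 2 or PH80_G+H replicate 2 (0 each). Without PH80_G+H replicate 1 there was 1 call, of a gene outside the 15, so 0 of these were left, without PH80_G+H replicate 3 there were 3, all among the 15, and 26 and 24 were made without PH80_HC replicate 1 or 3. There were 0 with every library at the same total, 7 when that total left out the 50 most abundant genes, 0 without the intensity trend, 40 with the length and GC trend removed, 24 without the library with the steepest length trend of each group, 11 with edgeR and 203 with DESeq2 (99 up and 104 down).

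Interferon response genes were higher in PH80_G+H, 16 of 17 with a positive difference (median log2 difference 0.89). Ifit1, Usp18 and Irgm1 were among those that rose (3.21-, 2.4- and 2.15-fold), and 11 genes rose adjusted over the list alone. The list had an adjusted p = 1.89e-15 at the preset correlation, an adjusted p = 0.0779 with an estimated correlation and an adjusted p = 0.00358 with fry. Against PH70 the same list was higher as well (adjusted p = 3.07e-17, and adjusted p = 0.0712 with an estimated correlation), with 13 genes past adjusted over the list alone.

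Mitosis genes were lower in PH80_G+H than in PH80, with all 29 negative (median -1.23) and all 29 past adjusted over the list alone. Of these, 0 passed over all genes in limma, 29 had an unadjusted p under 0.05, 0 passed by edgeR and 19 by DESeq2. The list had an adjusted p = 5.3e-26, and an adjusted p = 0.176 with an estimated correlation. The mean of the list above PH70 was -0.58, -0.10 and -0.80 in PH80_G+H replicates 1 to 3. Cdk1 was at 903 ± 218 against 2486 ± 699 (log2 difference -1.45, SE 0.27, adjusted p = 0.065), and Mki67 had a log2 difference of -0.87 (SE 0.33, adjusted p = 0.347).

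Hepatocyte function lists were higher than in PH80, though outside the clock list none of their genes passed over all genes tested in limma or edgeR. DESeq2 called 4 genes of drug metabolism, 2 pericentral markers and 1 each of gluconeogenesis and glycogen, fatty acid oxidation, the urea cycle list and periportal markers, all higher. Gluconeogenesis and glycogen had all 14 genes positive and 7 past adjusted over the list alone (list adjusted p = 1.57e-06, and adjusted p = 0.0779 with an estimated correlation). Drug metabolism (9 of 23 adjusted over the list alone) and pericentral markers (6 of 16) had list adjusted p = 2.74e-08 and 3.21e-06, and adjusted p = 0.176 for both with an estimated correlation. Fatty acid oxidation and growth hormone genes had list adjusted p = 1.21e-05 and 0.00022, and adjusted p = 0.327 for both with an estimated correlation. Bile acid genes and hepatocyte transcription factors had list adjusted p = 0.000136 and 0.00799, and adjusted p = 0.176 for both with an estimated correlation. Secreted proteins, the urea cycle list and periportal markers had list adjusted p = 0.00032, 0.00131 and 0.0158, and adjusted p = 0.404 for each with an estimated correlation. Clock genes, of which Dbp and Nr1d1 rose (7 adjusted over the list alone), had list adjusted p = 7.13e-05, and adjusted p = 0.187 with an estimated correlation. Hnf4a transcripts, at 12248 ± 1633, differed from PH80 by 0.30 on the log2 scale (SE 0.23, adjusted p = 0.679), and Cyp2e1, G6pc and Cebpa by 1.28, 1.30 and 0.80 (adjusted p = 0.199, 0.139 and 0.227).

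Among cell type lists in PH80_G+H, macrophage (median -0.38), fetal liver (-0.95) and cholangiocyte markers (-0.74) were lower with list adjusted p = 0.0062, 0.012 and 0.0324, and adjusted p = 0.542, 0.198 and 0.542 with an estimated correlation. Sinusoidal endothelial markers (median 0.20) were higher with list adjusted p = 0.037, 0.16 once the length and GC trend was removed, and adjusted p = 0.665 with an estimated correlation. The p53 targets and cholesterol synthesis were higher with list adjusted p = 0.00131 and 0.00799, and adjusted p = 0.404 and 0.621 with an estimated correlation. The other 17 lists had adjusted p-values from 0.0824 to 0.895, including 0.895 for neutrophil and 0.546 for pan-endothelial markers, and for apoptosis and necroptosis the test was below 0 with a median of 0.06. Csf3r, Vegfa, Alb, Cyp7a1, Stab2 and Pecam1 differed by -0.37, -0.08, 0.48, 1.34, 0.15 and 0.15, none past the threshold in limma. In the 34 lists without a call, 118 of 572 genes had an unadjusted p under 0.05, with 0 calls by edgeR and 38 by DESeq2.

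The treated arms were set beside the larger resection gene by gene. Both comparisons use the PH80 libraries, which gives opposite signs and shared genes by chance, so counts are set against 100 simulations without effects, in which as many genes were taken by the smallest p in each direction. Of the 137 genes that rose in PH80 against PH70, 131 were lower in PH80_HC than in PH80 (simulated 112 to 128) and 131 in PH80_G+H (111 to 132). Of the 343 that fell, 331 (299 to 325) and 340 (299 to 322) were higher. Genes called down by the larger resection and up in PH80_HC numbered 54, among them Dbp and Cyp2e1 (simulated 26 to 45), and those called up and then down numbered 15 (1 to 11). For PH80_G+H these were 9, among them Dbp and Nr1d1 (4 to 13), and 1 (0 to 1), which lie within the simulated ranges. The arms themselves shared 4 genes that rose against PH80 (1 to 12), which lies within its range too. No effect of the larger resection was simulated either, so a count within a range does not show that chance alone gave it.

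Across genes, which are not independent replicates, log2 changes of PH80 against PH70 were correlated with those of PH80_HC against PH80 at r = -0.521 (simulated -0.510 to -0.467) and with those of PH80_G+H against PH80 at r = -0.741 (simulated -0.510 to -0.461). The covariances were -0.158 and -0.199, against simulated -0.0607 and -0.0606, so that the differences were -0.0973 and -0.139. Between the arms, each against PH80, r was 0.431 (simulated 0.505) and the covariance 0.0991 (simulated 0.0607, difference 0.0384). The simulated genes vary independently, whereas real libraries share axes of variation, so these ranges are too narrow and a value just outside them does not count as an excess. With the PH80 libraries split between the comparisons, 1 for one and the other 2 for the other in 6 ways, no library is shared. Then r of PH80 against PH70 lay between -0.449 and -0.0277 with PH80_HC against PH80 (mean -0.245, simulated means -0.0247 to 0.027) and between -0.450 and -0.317 with PH80_G+H against PH80 (mean -0.378, simulated -0.0255 to 0.0262). Between the arms it lay between -0.117 and 0.324 (mean 0.119, simulated -0.0323 to 0.0211), so that its sign there depends on the split. For PH80 against PH70 and PH80_HC against PH80_G+H, which share no library, r was 0.135 (simulated -0.000661).

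Set against each other, PH80_HC had 11 genes higher and 21 lower than PH80_G+H (1710 at an unadjusted p under 0.05). Cux2, a transcription factor (237 ± 134 against 6.37 ± 1.55, 29.7-fold, adjusted p = 0.0371, chromosome 5, 121856366 to 122050102), the chemokines Ccl5 (243 ± 86.8 against 19.7 ± 9.74, 12.1-fold) and Cxcl9 (512 ± 220.2 against 89.8 ± 2.51, 5.32-fold) and the thioesterase Acot3 (log2 change 2.27) were higher in PH80_HC. Oasl1 (379 ± 134 against 1600 ± 361, 4.33-fold, adjusted p = 0.0188), Mup1, Mup7 and Nat8f5 (log2 changes -2.99, -2.61 and -1.94) were lower. Of 17 interferon response genes 7 were lower in PH80_HC, or 12 lower and 1 higher adjusted over the list alone, among them Ifit1 and Usp18, chosen after their values were seen (log2 changes -1.89 and -1.33). For the list, camera gave an adjusted p = 1.47e-13, and an adjusted p = 0.143 with an estimated correlation. The 32 calls became 16 and 11 without PH70 replicate 1 or 2, 21 and 2 without PH80_HC replicate 2 or 3, 5, 5 and 3 without PH80_G+H replicate 1, 2 or 3, and 59 without PH80 replicate 2. They became 19 with the stricter filter, 16 without the library with the steepest length trend of each group and 303 with DESeq2.

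Each treated arm was also set against PH70. In PH80_HC 14 genes were higher and 15 lower (1984 at an unadjusted p under 0.05), with Apoa4, an apolipoprotein of lipid transport (97000 ± 53568 against 10311 ± 1707, log2 change 3.08, SE 0.40, adjusted p = 0.0178), Cux2, Ccl5 and Akr1b7 (log2 changes 4.74, 3.88 and 3.76) higher, and Rgs16, Mup1, Nr4a1 and Mup21 (-4.45, -2.94, -2.87 and -2.64) lower. In PH80_G+H 1 gene differed, Dsg1c, a desmosomal cadherin chosen after its values were seen (5.05 ± 3.36 against 80.01 ± 17.7, log2 change -3.91, SE 0.48, adjusted p = 0.0144), with 750 genes at an unadjusted p under 0.05. The first count, 29, became 8, 2 and 1 without PH70 replicate 1, 2 or 3, 6 and 6 without PH80_HC replicate 1 or 3, 6, 16 and 4 without PH80_G+H replicate 1, 2 or 3, 54 without PH80 replicate 2, 17 with the stricter filter, 8 without the intensity trend, 15 with edgeR and 253 with DESeq2. The second, 1, became 0 without any 1 of the PH70 libraries, without PH80_G+H replicate 1 and with the stricter filter, 13 with the compared groups alone, 9 without the library with the steepest length trend of each group, 6 with the length and GC trend removed and 66 with DESeq2.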

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

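Removal of the trend with transcript length and GC and the fit without the steepest library of each group (PH70 replicate 3, PH80 replicate 1, PH80_HC replicate 3 and PH80_G+H replicate 2) were chosen after seeing the data. The cause of the shifts given here was not tested, except that fits with fewer libraries have less power. Counts are given in the order PH80 against PH70 (480), PH80_HC against PH80 (112), PH80_G+H against PH80 (15), PH80_HC against PH80_G+H (32), PH80_HC against PH70 (29), PH80_G+H against PH70 (1) and the F test (232), where a setting moved them by over 1.5 times.

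With every library at the same total the counts were 237 (127 up and 110 down, or 53.6% up against 28.5%), 72 (23.6% up against 73.2%), 0 (1316 at an unadjusted p under 0.05 as deposited, 11 by edgeR and 203 by DESeq2) and, for the F test, 139. Leaving the 50 most abundant genes out of the total gave 55 (40% up) for PH80_HC against PH80 and 7 for PH80_G+H against PH80, and 45.5% up for PH80 against PH70. The share up in PH80_HC against PH80_G+H was 34.4%, and 17.9% and 17.2% under these scalings, and against PH70 it was 48.3%, 23.8% and 28.6%. The same total moved the median of all genes to 0.13, -0.31, -0.21 and -0.20 for PH80 against PH70 and for PH80_HC against PH80, PH80_G+H and PH70, and without the top genes it moved those of PH80_HC to -0.20, -0.14 and -0.15, so that directions there are relative to the scaling. DESeq2 called 952, 508, 203, 303, 253, 66 and 1226 genes, with 479 of the 480 and 110 of the 112 shared, and 48.8%, 55.8%, 62.8% and 56.1% up in the last 4 pairwise comparisons. EdgeR moved PH80_HC against PH70 to 15 (33.3% up).

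Without the intensity trend the counts were 0, 8 and 106 for PH80_G+H against PH80, PH80_HC against PH70 and the F test. The stricter filter gave 19, 17 and 0 for the last 3 pairwise comparisons, and a pseudocount of 8 and quantile normalization gave 3 and 2 for PH80_G+H against PH70. The compared groups alone gave 2 for PH80_HC against PH80 and 13 for PH80_G+H against PH70. Removal of the length and GC trend gave 219 (110 of the 112 shared), 40 and, for PH80_G+H against PH70, 6, and 445 of the 480 were shared among 656. Without the steepest libraries the counts were 302 (231 shared), 61 (42 shared), 24 (7 shared), 16 for PH80_HC against PH80_G+H, 9 for PH80_G+H against PH70 and 137 for the F test.

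Leaving out 1 library gave 61 (without PH70 replicate 2) to 727 (without PH80_HC replicate 3), 28 (PH80 replicate 1) to 125 (PH70 replicate 3), 0 (PH70 replicate 2, PH80 replicate 1 or 2, or PH80_G+H replicate 2) to 26 (PH80_HC replicate 1), 2 (PH80_HC replicate 3) to 59 (PH80 replicate 2), 1 (PH70 replicate 3) to 54 (PH80 replicate 2), and 0 (any PH70 library or PH80_G+H replicate 1) to 6 (PH80_HC replicate 3). For the F test it gave 27 (PH70 replicate 2) to 281 (PH80_HC replicate 3), with 85 without PH70 replicate 1, 95 without PH80 replicate 1 and 124, 146 and 84 without PH80_G+H replicates 1 to 3.

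Replicate numbers, taken from the titles, gave no clear pairing of the libraries. The deposited columns carry other numbers, which were not tested, so pairing or a batch is not excluded. Deviations from the group means were correlated between libraries with the same number from -0.367 to 0.373 (6 of 18 pairs over 0.1), and 1 of 12 libraries was closest to its own number. With the number as a block the counts were 293, 65, 9, 8, 10 and, for the F test, 107.

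The correlation of PH80 against PH70 with PH80_HC against PH80 (-0.521) was -0.658 without the steepest libraries and -0.646 to -0.401 without 1 library. That with PH80_G+H against PH80 (-0.741) was -0.796 with the stricter filter, -0.696 without the steepest libraries and -0.814 to -0.662 without 1 library. Of 36 lists 15, 19 and 19 passed in the 3 main comparisons with the preset correlation, 0, 0 and 0 with an estimated correlation, 9, 9 and 2 with fry, and 13 to 18, 18 to 22 and 16 to 24 without 1 library. Erythroid markers in PH80_HC against PH80 turned to lower with the stricter filter (adjusted p = 0.901, with fewer genes tested). Lymphocyte markers in PH80_G+H against PH80 turned from lower (adjusted p = 0.551) to higher (adjusted p = 0.000363) without the steepest libraries.

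Of the named calls, 15 of 60, 2 of 28 and 0 of 13 in the 3 main comparisons were kept in all of their alternatives, among them Dbp, Nr1d1, Rgs16, Mybl1 and Gdf15 for PH80 against PH70, and Inava and Npas2 for PH80_HC against PH80. The number of alternatives that lost a call is printed beside some calls alone, and others were lost as often. In PH80_HC against PH80, Cd74, Jchain and Oasl1 were each lost in 12 of 27, and Gbp2 and Slc27a5 in 13. In PH80 against PH70, Gbp10 and Ghr were lost in 10 and 12 of 27. None of 307 named values reversed past the threshold. Without 1 library 3214 kept their side of it, 419 lost and 51 gained a call. The stricter filter gave no value for genes below it. In simulated counts with the real library sizes, 34.3% of genes changed 2-fold were recovered in PH80 against PH70. The changed genes had a mean value of at least 50. Absence of a call therefore does not show absence of such a change.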

Other observations

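Tests of the scaling, of the length and GC trend, of hepatocyte share, of clock phase, of macrophage RNA, of lymphocyte RNA and of the contrast of interferon genes against PH70 were chosen only after the results were seen. Other splits of the libraries, single libraries and the correlation with mitosis genes were fixed before theirs were.

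At the preset correlation some immune lists and cholesterol synthesis differed between the treated arms. Lymphocyte markers were higher in PH80_HC than in PH80_G+H (median log2 difference 1.91, 15 of 17 positive, 9 past adjusted over the list alone, list adjusted p = 3.01e-07, and adjusted p = 0.685 with an estimated correlation), as were macrophage markers, with all 19 positive (median 0.80, 8 past adjusted over the list alone, list adjusted p = 5.33e-06, and adjusted p = 0.685 with an estimated correlation). Cholesterol synthesis was lower, with all 20 genes negative (median -0.86, 11 past adjusted over the list alone, list adjusted p = 4.7e-10, and adjusted p = 0.685 with an estimated correlation). Neutrophil markers did not pass (median -0.13, list adjusted p = 0.644). Interferon response genes were lower in PH80_HC at the preset correlation, but did not pass with an estimated one. Stellate cell and matrix genes had a median of -0.75 (list adjusted p = 5.22e-05, and adjusted p = 0.706 with an estimated correlation).

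Against PH70, PH80_HC had higher lymphocyte (median 1.93), neutrophil (1.70), macrophage (0.80) and acute phase genes (1.22), with list adjusted p = 1.95e-06, 0.000121, 3.03e-05 and 4.37e-06, and adjusted p = 0.486 for each with an estimated correlation. Neutrophil markers were higher in PH80_G+H than in PH70 as well (median 0.90, list adjusted p = 9.1e-06, and adjusted p = 0.839 with an estimated correlation). Libraries of a group differed widely in these markers. Their mean above the PH70 mean was 1.72, 0.49 and 2.12 in PH80_G+H replicates 1 to 3, and 0.99, 1.11 and 2.29 in PH80_HC. In PH70 it was -0.47, 0.04 and 0.43, so PH80_G+H replicate 2 was near PH70 replicate 3. Single members that rose in PH80_HC against PH70, chosen after their values were seen, were Gzmb, a protease of cytotoxic lymphocytes (54.2 ± 28 against 5.8 ± 3.11, log2 change 3.04, SE 0.56, adjusted p = 0.0474), and Prtn3, a neutrophil protease (log2 change 2.31, adjusted p = 0.0435). Gdf15 and Dusp1 fell in PH80_HC against PH70 (log2 changes -1.80 and -1.96, adjusted p = 0.0183 and 0.026).

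Clock genes moved in opposite directions between PH80 and PH70. A lower share of hepatocyte RNA in PH80 was taken to lower the antiphase set (Npas2, Cry1 and others) as well, and that set rose. Genes of other cells can rise with such a share. Which cells express Npas2 and Cry1 was not tested, so that cause stays open. The mean of 4 genes of the antiphase set was higher by 0.815 (SE 0.132). Npas2 and Cry1 are the members of that set that passed as higher, and its mean rests on them. The mean of 9 genes of the Dbp phase was lower, at -1.92 (SE 0.335). The difference of 2.73 (SE 0.375) stayed at 2.7 or more (SE 0.447) without any 1 PH80 library. A different clock phase at sampling may account for it, which is a hypothesis found and tested on the same data. The same difference was -2.2 for PH80_HC and -1.66 for PH80_G+H against PH80, and 0.536 and 1.08 against PH70 (SE 0.375 each). As the time of day of sampling is not given in the sources used here, a shift of the clock by the resection and a different sampling time remain open.

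Hepatocyte function genes (159 over the lists) were lower in PH80 than in PH70 by a mean log2 difference of -0.571 (SE 0.118). The difference stayed at -0.451 (SE 0.148) with every library at the same total and at -0.6 (SE 0.118) with the length and GC trend removed. Neither that scaling nor the trend as fitted is likely to be the whole cause. The axis of the first principal component is not excluded. With the trend removed, a split of the 12 libraries along it still called 1008 genes by the F test. A lower share of hepatocyte RNA would raise markers of every other cell type alike, and sinusoidal endothelial minus macrophage markers gave -0.663 (SE 0.297), but -0.571 (SE 0.32) with the trend removed, which leaves it open. A decrease that goes with mitosis genes library by library gave r = -0.508 for deviations from the group means (Spearman rho -0.392, exact permutation p = 0.253 over 1296 permutations), and over all 12 libraries r = -0.693 (permutation p = 0.0123), rho = -0.531 (permutation p = 0.08), and r = -0.553 without the 2 farthest libraries. The bound set beforehand, a p of 0.05 or more, was wrong as a ground for exclusion, because a p that misses the threshold in 12 libraries excludes nothing, so this too stays open, as does an effect of the resection itself.

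Interferon response genes were higher in PH80_G+H than in PH80 by 0.87 (SE 0.135), and by at least 0.822 (SE 0.156) without any 1 PH80_G+H library. More macrophage RNA is unlikely as the cause, since the contrast of these markers was -0.511 (SE 0.367), 1.38 below that of the interferon list (SE 0.419), and still 1.41 below it (SE 0.552) without the steepest libraries. More lymphocyte RNA stays open. The contrast of these markers was -0.183 (SE 0.519), 1.05 below that of the interferon list (SE 0.472), but it turned to 0.6 (SE 0.509), 0.415 below (SE 0.475), without the steepest libraries. These include PH80 replicate 1, with the highest mean of lymphocyte markers in its group (1.19 above PH70). They also include PH80_G+H replicate 2, with the lowest in its group (-0.56). The turn rests on leaving out these libraries. PH80_HC had more of these markers than PH80_G+H (1.53, SE 0.519) and lower interferon genes (-0.963, SE 0.135), which counts against lymphocyte RNA as the cause only if these cells are in the same state in both arms. A low level in PH80 alone is argued against by a contrast of 0.78 (SE 0.135) against PH70. A response to G-CSF with HNF4a, or to the way these were given, which is not given in the sources used here, is a hypothesis that was not tested, since the labels name no library as a carrier control.

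Regrouping of the libraries bears on these counts. For each pairwise comparison of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real split gave 480, 112, 15, 32, 29 and 1 genes and the highest other gave 0, 1, 0, 0, 1 and 0, in the order PH80 against PH70, PH80_HC and PH80_G+H against PH80, PH80_HC against PH80_G+H, and PH80_HC and PH80_G+H against PH70, so that 1 split of 10 reached the real count in each. For lists past camera at the preset correlation, 3, 3 and 1 of 10 splits gave as many as the real 15, 19 and 19, and the highest other gave 18, 20 and 18. For the F test 2 of 100 splits, the real one included, gave at least 232 genes, a share under 0.05. Few regroupings reach the real count. Chance is still not excluded, since 1 regrouping called more genes and the libraries of a group may not be separate animals. The other of the 2 splits called 1416 genes, and 1008 with the length and GC trend removed against 341 for the real split, while the next highest gave 2. That split orders the libraries along the first principal component. The groups hold part of this axis, since each PH80 library scores above each PH70 library, and libraries of 1 group also differ along it.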
